A study of Mus musculus and Drosophila melanogaster with 55 samples.

How the data were processed

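The 55 samples comprise 30 tissue RNA libraries, 4 RNA and 4 ribosome footprint libraries of C2C12 cells, 6 fraction libraries of C2C12 cells, 6 fraction libraries of fly S-2R+ cells, and 5 lists of binding clusters from crosslinking and immunoprecipitation (CLIP). C2C12 is a mouse myoblast line and S-2R+ is a Drosophila cell line. Per the labels' protocols, C2C12 fractions were taken with 0.015% digitonin (cytosol), 0.5% Triton X-100 (membrane) and 1 M NaCl (insoluble), fly fractions came from hypotonic lysis and ultracentrifugation, and ribosomes were collected through a sucrose cushion. Per the labels' protocols, CLIP used a polyclonal antibody to Mbnl on tissue of males at 16 weeks of age. For C2C12 whole-cell RNA the labels' descriptions name poly(A) RNA and the labels' protocols name removal of ribosomal RNA, so the selection is unsettled. Per the submitters' processing notes, reads were mapped with Bowtie, with no version stated, to mm9 for mouse and dm3 for fly. The annotation, the counting and the cluster calling are not stated in the submitters' processing notes.

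Expression values are RPKM, reads scaled by transcript length and library total, as deposited by the authors. Within each fraction the control and depleted columns deposited by the authors were 0 for the same genes and close after sorting, with 54.4% to 73.9% of sorted values within 1% of each other. The fraction tables therefore look normalised together, by a method that is not stated, and the total change of a fraction is not read from them. The deposited cluster lists carry a score of 1e-06 for every cluster, which ranks nothing. Cluster starts were read as counted from 0 and are printed as counted from 1.

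Read counts are not given, so no counting interval could be set on RPKM. The depth of the tissue libraries relative to WT library 1 of the same tissue was estimated from genes above 0 in at most 4 libraries, whose values are mostly a few reads. Relative depth ran from 0.92 to 2.16 in brain, 0.65 to 2 in heart and 0.87 to 1.37 in muscle.

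Tissue values were taken as log2(RPKM + 0.5) for genes with a mean of at least 1 RPKM in the tissue. KO and WT libraries, 5 against 5, were compared by limma 3.58.1 with an intensity trend in R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as a call. The difference of the KO effect between tissues was a limma contrast over all 30 libraries, for genes that passed the minimum in both tissues. Replicate letters and numbers are not stated to pair mice across tissues, and blocking on them was an alternative. Gene lists with at least 5 tested members were compared with all other genes by camera in limma, with a preset correlation of 0.01, and adjusted over the lists of the tissue. Camera with an estimated correlation and fry were alternatives. Fry tests a list against no change, not against all other genes.

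Before the data were examined, 45 gene lists were fixed (32 for tissues, 17 for myoblasts and 7 for fly cells, some for more than 1 use), together with the rule for the genes named in the text. The rule takes the Mbnl family, the 10 highest and 10 lowest log2 fold changes among called genes without overlap of KO and WT libraries, up to 4 called members per list, and the 5 smallest adjusted p per tissue contrast. For the cell comparisons it takes the 8 highest and 8 lowest changes and up to 4 members of each list that lay outside the random range. Genes named outside this rule are marked as chosen after their values were seen.

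The cell comparisons have 1 library per condition and therefore no test per gene. Ratios were taken as log2(RPKM + 1) for genes with a mean of at least 5 RPKM in each assay used, and counts give changes of at least 2-fold. Translation is given as the footprint ratio minus the RNA ratio. The median of each list was set against the medians of 10000 random lists matched on mean expression in 20 bins, and called above or below when outside the central 95% (percentiles 2.5 to 97.5). These ranges cover the choice of genes, not the variation between cultures.

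Clusters were intersected with bedtools 2.31.1, with 1 bp on the same strand as an overlap and clusters shifted by 1, 2, 5 or 10 kb either way as background. Shares carry 95% Wilson intervals, which cover counting error only. Genes with clusters were compared with random genes matched on expression, and in tissues also by exact permutation over all 252 assignments of genotype, two-sided. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

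The tissue test was checked on simulated data with the spread of each tissue and 50 changed genes at each fold change in 20 runs. Genes were drawn independently of each other, so libraries that stand apart and correlation between genes were not covered. The test found the following shares for such data only. It found 1.8% to 3.9% of genes changed 1.25-fold, 24.2% to 30.1% at 1.5-fold, 64% to 72.1% at 2-fold and 94.4% to 96.8% at 4-fold, with 4.96% to 5.65% of calls false. The contrast of muscle and heart found 12.9% of genes at 1.5-fold and 51.4% at 2-fold, with 12.2% of calls false, above the nominal rate. Alternatives covered pseudocounts, expression minimums, scaling, library weights, a joint fit, each library left out in turn, gene lists without the split genes, cluster overlap and matching. Alternative splicing was not analysed here, since it needs values per exon.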

Results

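Muscleblind-like (Mbnl) proteins bind RNA and regulate alternative splicing. The series set out to find what these proteins do across the transcriptome of mouse tissues, of a mouse myoblast line and of a fly cell line. RNA was measured in brain, heart and muscle of Mbnl1 knockout (KO) and wild-type (WT) mice, with 5 libraries per genotype and tissue. C2C12 myoblasts with short hairpin RNAs against Mbnl1, Mbnl2 or both, and a control, gave 1 RNA library and 1 ribosome footprint library each. Cytosolic, membrane and insoluble fractions came from control and doubly depleted C2C12 cells and from control and mbl-depleted fly S-2R+ cells, with 1 library each. CLIP clusters came from B6 brain, 129 brain, heart, muscle and C2C12 cells.

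Total RPKM per library ran from 253537 to 387545 in brain, 359105 to 415134 in heart and 398702 to 495282 in muscle. The 10 most abundant genes took 3.15% to 4.01% of the RPKM in brain, 14.8% to 18.7% in heart and 35% to 38.9% in muscle. Totals in C2C12 cells were 376728 to 402746 for RNA and 535368 to 557227 for footprints. Absolute read depth is unknown, and the libraries outside the tissues have no replicates.

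Mbnl1 RNA itself (Entrez 56758) fell in KO heart from 36.0 ± 6.33 to 14.9 ± 3.87 RPKM (mean ± SD, n = 5 per genotype, log2 fold change -1.27, limma adjusted p = 0.00854). It fell in KO muscle from 67.1 ± 6.67 to 37.7 ± 12 RPKM (log2 fold change -0.87, adjusted p = 0.00878). In brain the means were 22.4 ± 2.87 in WT and 17.4 ± 2.62 in KO, which did not pass the test (log2 fold change -0.36, adjusted p = 1). Mbnl2 (Entrez 105559), the paralog with 58.2 RPKM in KO brain, had log2 fold changes of 0.03 in brain, 0.04 in heart and -0.04 in muscle, none of which passed (adjusted p = 1, 0.914 and 0.877). Mbnl3 lay under the expression minimum in all 3 tissues.

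**Figure D1:**
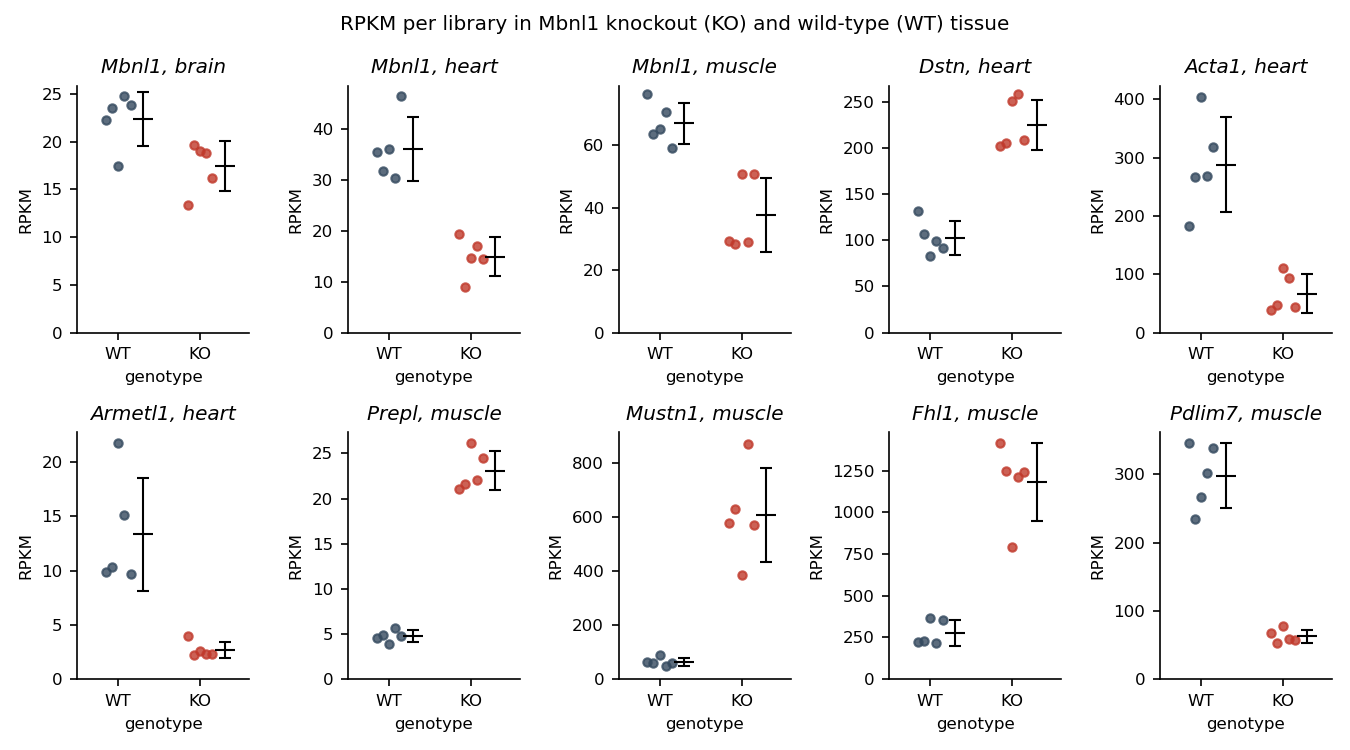
RPKM (linear axis from 0) in single WT (dark) and KO (red) libraries, with the mean and SD of each group beside the points, n = 5 per group. Panels show Mbnl1 in brain, heart and muscle, Dstn, Acta1 and Armetl1 in heart, and Prepl, Mustn1, Fhl1 and Pdlim7 in muscle. Mbnl1 values overlapped between genotypes in brain and did not in heart or muscle, and the means of Mustn1 in muscle were 63.9 in WT and 608 in KO.

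In brain, values of 2 of 11656 genes differed by genotype, both of ribosomal proteins, against 7 genes with a joint fit of the 30 libraries and 44 with library weights. Rps3a (Entrez 20091) stood at 8.43 to 33.7 RPKM in KO libraries and 0 to 0.25 in WT (log2 fold change 4.66, adjusted p = 3.22e-05). Rpl34 stood at 4 to 11 RPKM in KO and 0 to 0.66 in WT (log2 fold change 3.55, adjusted p = 0.000321). A value near 0 for a gene that every cell uses is not believable as expression, so the WT values and these fold changes are not read as such in any tissue, and 39 of the 74 ribosomal protein genes in the table reached the minimum. The list of cytosolic ribosomal proteins had 30 of 39 tested members higher in KO, with a median log2 fold change of 0.17, a mean of 0.38 and a camera adjusted p of 5.53e-09. The mean and this p include Rps3a and Rpl34, which raise the mean, so the median is the better guide to the other members. This p is not read for those members. Its call count was 2 over all genes and 3 when adjusted over the list alone, the added gene being Rpl23 at 23.6 RPKM in KO and 14 in WT, named after its values were seen. Without KO library a the adjusted p of this list was 0.1, and it was 0.744 with an estimated correlation.

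The other brain lists that passed had medians of 0.09 to 0.14. Oxidative phosphorylation genes were higher in 35 of 41 members (median 0.09, camera adjusted p = 0.00717), but the direction reversed without KO library a (adjusted p = 0.0578), and the adjusted p was 0.183 without WT library 1 and 0.744 with an estimated correlation. Markers of smooth muscle and pericytes were higher in 9 of 10 members (median 0.14, adjusted p = 0.00594), which became 0.0518 without KO library c, 0.0535 without WT library 3 and 0.293 with an estimated correlation. Acta2, the smooth muscle actin, was the single member called when adjusted over the list alone, at 18.8 RPKM in KO and 12.3 in WT, named after its values were seen. Endothelial markers were higher in 8 of 12 members (median 0.09, adjusted p = 0.0415, no member called either over all genes or adjusted over the list alone), and lost the call without KO library b (adjusted p = 0.163), KO c (0.196), KO d (0.246), WT 2 (0.0723), WT 3 (0.0741) or WT 5 (0.0883). With all libraries that adjusted p was 0.744 with an estimated correlation. Known Muscleblind splicing targets were higher in 4 of 28 members (median -0.12) and did not pass (adjusted p = 0.137), though they passed as lower without KO library b (0.0379), KO c (0.0264), KO d (0.034) or WT 3 (0.0179). Further brain lists that did not pass with all libraries passed with 1 left out. Without KO library a these were matrix genes as higher (adjusted p = 4.75e-05, against 0.119) and ER chaperones (0.0203, against 0.606), oligodendrocyte markers (0.0157, against 0.184) and glycolysis (0.0207, against 0.727) as lower. Matrix genes also did without WT 4 (0.0152) and, at 0.05 when rounded, without WT 1, as did macrophage markers as lower without WT 1 (0.05 when rounded). Interferon response genes passed as higher without KO b (0.0187), excitatory synapse genes as lower without KO e (0.0241) and immediate early genes as lower without WT 4 (0.0362). With all libraries these 8 lists had 0 members called over all genes, and 2 lower among macrophage markers, 1 lower among immediate early genes and 0 in the others when adjusted over the list alone. At an unadjusted p under 0.05, limma gave 435 brain genes (3.73%), where chance gives 583 (5%). Brain libraries split without overlap in 1.49% of tested genes, where chance gives 0.79%.

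In heart, 31 genes rose and 46 fell in KO among 10304 tested, 77 in all, against 221 with the joint fit and 326 with library weights. Acta1, the skeletal alpha-actin, fell from 288 ± 81.4 to 66.7 ± 33.1 RPKM (log2 fold change -2.19, adjusted p = 0.00518). Mybpc2, the fast skeletal myosin-binding protein C, fell from 12.6 ± 1.48 to 2.60 ± 0.828 RPKM (log2 fold change -2.12, adjusted p = 5.86e-05). Cabc1, a mitochondrial kinase of coenzyme Q synthesis, fell from 277 ± 31.2 to 81.0 ± 6.98 RPKM (log2 fold change -1.76, adjusted p = 1.58e-06). Ankrd23, a stretch-responsive ankyrin repeat protein of the sarcomere, fell from 271 ± 55.7 to 94.1 ± 13.0 RPKM (log2 fold change -1.51, adjusted p = 0.000143). Dstn, the actin-depolymerising factor destrin, rose from 102 ± 18.4 to 225 ± 27.2 RPKM (log2 fold change 1.14, adjusted p = 0.000931).

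Armetl1, a neurotrophic factor of the endoplasmic reticulum (ER), fell in KO heart from 13.3 to 2.68 RPKM and the Hippo pathway kinase Lats2 fell from 8.34 to 2.94. Casq1, the calcium-binding protein of fast fibres, fell from 22.8 to 9.27 RPKM, and the metalloprotease Adam19 fell from 6.59 to 1.79 RPKM. Sec61a2, a subunit of the ER translocon, rose from 5.37 to 12 RPKM. Fbp2, the muscle fructose bisphosphatase, rose from 10.4 to 20.5 RPKM, with an adjusted p of 0.0168 that reached 0.0536 without KO library c, KO library d or WT library 3. The RPKM of Rps3a were 23.2 to 33.3 in KO heart and those of Rpl34 were 4.59 to 18.8, while both were listed at 0 in all 5 WT libraries. Selenbp2, a selenium-binding protein, was listed at 0 in all 5 KO hearts and stood at 3.04 to 5.06 RPKM in WT.

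Genes of fast fibres had 2 of 6 tested members lower in KO heart, Mybpc2 and Casq1, and 1 higher and 2 lower when adjusted over the list alone. Their camera adjusted p was 0.112, or 0.0435 without KO library e, and it was 0.856 by camera with an estimated correlation. Against no change, their fry adjusted p was 0.00326. The cardiac stress list had 2 of 16 members lower, Acta1 and Ankrd1, and 4 when adjusted over the list alone, with a median of -0.21 and an adjusted p of 0.122. Known Muscleblind splicing targets had 2 members higher and 1 lower of 27 tested, and 2 higher and 8 lower when adjusted over the list alone, with a camera adjusted p of 0.382. Among them Pdlim3, a Z-disc protein, stood at 90.9 RPKM in KO and 46.4 in WT (adjusted p = 0.0144, and 0.0508 without KO library c).

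The heart lists that passed camera were interferon response, extracellular matrix, oxidative phosphorylation and fatty acid oxidation. Interferon response genes were higher in 21 of 22 members (median 0.38, camera adjusted p = 7.9e-08), with 0 members called over all genes and 4 higher when adjusted over the list alone. These 4, named after their values were seen, were Irf7 (11.3 RPKM in KO, 3.79 in WT), Rtp4 (8.28 and 3.91), Oasl2 (4.96 and 1.86) and Ifit3 (1.89 and 0.552). In KO library a this list lay 0.85 above the other KO libraries, and without that library its adjusted p was 0.000331. Matrix genes were lower in 33 of 37 members (median -0.30, adjusted p = 0.000728), with Col4a2 lower over all genes (34.8 RPKM in KO, 60.8 in WT, adjusted p = 0.0448) and 5 members lower when adjusted over the list alone. Smooth muscle and pericyte markers were lower in 10 of 11 members (median -0.26, 0 called over all genes, 1 higher and 3 lower when adjusted over the list alone) and did not pass (adjusted p = 0.0934), though they did without KO library e (0.0142) or WT library 5 (0.019). Adipocyte markers were lower in 7 of 10 members (median -0.90, 0 called over all genes, 3 lower when adjusted over the list alone) and did not pass either (adjusted p = 0.112), though they did without KO library e (0.00885) or WT library 4 (0.0294). Against the other libraries of the genotype their median lay at 1.49 in WT library 2, 1.34 in KO library e and -1.25 in WT library 4. Oxidative phosphorylation genes were higher in 26 of 42 members (median 0.03, adjusted p = 0.00166) and fatty acid oxidation genes in 13 of 20 (median 0.06, adjusted p = 0.018), with 0 members called in either list, also when adjusted over the list alone. All 4 lists that passed had an adjusted p of 0.856 with an estimated correlation.

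Libraries that stood apart moved with some of these heart lists. Macrophage markers in WT library 5 lay 2.58 above the other WT hearts in median, and without that library they passed as higher in KO (adjusted p = 0.000778, against 0.729 with all libraries). Without WT library 5 the adjusted p was 0.0886 for oxidative phosphorylation and 0.2 for fatty acid oxidation; oxidative phosphorylation gave 0.0529 without KO library b, and fatty acid oxidation 0.0999 without KO library a. Ribosomal protein genes in heart had 17 of 39 members higher, a median of -0.08 and a mean of 0.19 and did not pass (adjusted p = 0.112). They had 2 members called higher over all genes and 2 when adjusted over the list alone. The 2 called over all genes were Rps3a and Rpl34, which the mean includes though their fold changes are not read as expression. With these 2 genes included, the list passed with an adjusted p of 0.000331 without KO library a, 0.0193 without WT library 2 and 0.019 without WT library 5. Circadian clock genes (1 member higher over all genes, 4 higher and 1 lower when adjusted over the list alone) passed as higher without WT library 3 (0.0198, against 0.112). Without KO library e, 7 heart lists passed.

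The heart count was 77 with all libraries and 97 without WT library 5. It was 191 without KO library a, 34 without KO b, 25 without KO c, 28 without KO d, 32 without KO e, 49 without WT 1, 32 without WT 2, 28 without WT 3 and 46 without WT 4. Of 29 called heart genes under the naming rule, 15 kept the call with each library left out and 14 lost it at least once, among them Fbp2, Pdlim3, Ankrd1 and Col4a2. With each library scaled by median ratios 52 genes were higher and 30 lower, and with quantile normalisation 47 and 26, against a median log2 fold change of all heart genes of -0.09 as deposited. Of the 77 called genes, 75 had no overlap between genotypes, and 4.75% of tested genes had none, where chance gives 0.79%.

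In muscle, 389 genes rose and 571 fell in KO among 9219 tested, 960 in all, against 1397 with the joint fit and 1150 with library weights. Mustn1, a small nuclear protein of the musculoskeletal system, rose from 63.9 ± 15.1 to 608 ± 175 RPKM (log2 fold change 3.22, adjusted p = 7.98e-07). Fhl1, a LIM protein of slow and growing fibres, rose from 278 ± 76.8 to 1183 ± 233 RPKM (log2 fold change 2.11, adjusted p = 2.73e-05). Hspb7, a small heat shock protein, rose from 106 ± 43.5 to 594 ± 152 RPKM (log2 fold change 2.54, adjusted p = 0.000133). Pdlim7, a PDZ and LIM protein of the Z-disc, fell from 298 ± 47.6 to 62.7 ± 9.57 RPKM (log2 fold change -2.24, adjusted p = 7.98e-07). Pfkfb3, which sets the level of the glycolytic activator fructose 2,6-bisphosphate, fell from 80.7 ± 12.1 to 15.8 ± 6.95 RPKM (log2 fold change -2.40, adjusted p = 5.04e-05).

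Further genes that rose in KO muscle were the muscle LIM protein gene Csrp3 (94.7 RPKM in KO, 12.3 in WT), the calcium-dependent transcription factor Nfatc2 (17.4 and 2.68), the amino acid transporter subunit Slc3a1 (8.90 and 1.51) and the peptidase-like Prepl (23.1 and 4.76). Armetl1 fell from 23.3 to 1.78 RPKM, the potassium channel subunit Kcnab1 from 14.3 to 1.49 and the secreted Wnt modulator Dkk3 from 26.1 to 3.52, while the inflammatory caspase Casp12 had a log2 fold change of -2.26. Sln, the sarcolipin that inhibits the calcium pump, was listed at 0 in all WT muscles and stood at 2.92 to 10.7 RPKM in KO. Rps3a stood at 10.4 to 14.4 RPKM and Rpl34 at 4.95 to 11.4 in KO, and both were listed at 0 in WT.

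Known Muscleblind splicing targets had 5 of 30 tested members higher and 6 lower in KO muscle, and 5 higher and 7 lower when adjusted over the list alone, with a camera adjusted p of 0.486. The actin-binding Nrap rose from 307 to 501 RPKM. Clcn1, the muscle chloride channel, fell from 42.1 ± 6.10 to 21.1 ± 3.28 RPKM (adjusted p = 0.000678). Other splicing regulators had 1 of 23 members higher, Rbm38 (165 RPKM in KO, 111 in WT), and 2 lower, Cugbp2 (11.4 and 23) and A2bp1 (42.5 and 62.1), with the counts alike when adjusted over the list alone. The call of A2bp1 was lost in 7 of 10 fits with 1 library left out (adjusted p up to 0.0846).

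Genes of embryonic and regenerating muscle had 6 of 17 tested members higher and 0 lower in KO, and 7 higher when adjusted over the list alone (median 0.33, camera adjusted p = 0.00251). They included the adhesion molecule Ncam1 (5.89 RPKM in KO, 1.49 in WT), the stress-responsive Ankrd1 (12.7 and 3.08) and, named after its values were seen, the perinatal myosin Myh8 (5.20 and 2.46). The cardiac stress list had 4 of 10 members higher and 1 lower, and 5 and 1 when adjusted over the list alone (median 0.37, adjusted p = 0.00656), with Xirp1, an actin-binding repeat protein, at 42.6 RPKM in KO and 14.5 in WT. Both lists passed fry, a test against no change (adjusted p = 0.0135 and 0.0157). Against other genes, both had a camera adjusted p of 0.301 with an estimated correlation. The fast myosin Myh1 rose from 330 to 980 RPKM, while the fast fibre list as a whole had 2 members higher and 2 lower of 15 (2 and 3 when adjusted over the list alone, median -0.05, mean 0.08, adjusted p = 0.923). The slow fibre list went both ways, with Fhl1 and Csrp3 higher and the slow myosin light chain Myl2 lower (0.806 RPKM in KO, 6.52 in WT), at 3 higher and 1 lower of 10 and 3 of each when adjusted over the list alone (adjusted p = 0.28, and 0.0254 without KO library c). Among atrophy genes the growth inhibitor Mstn fell from 54.6 to 24.7 RPKM, as 1 of 3 lower and 0 higher among 17, with the counts alike when adjusted over the list alone (adjusted p = 0.254).

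ER chaperones and stress genes had 7 of 25 members higher and 2 lower, and 9 and 2 when adjusted over the list alone (median 0.28, camera adjusted p = 0.00481). Among those named after their values were seen, the chaperone Hspa5 stood at 111 RPKM in KO and 78.3 in WT, and Hsp90b1 at 58.3 and 44.6. Chac1, a glutathione-degrading enzyme induced in the stress response, fell from 80 to 36.1 RPKM. Matrix genes were higher in 31 of 39 members (median 0.28, adjusted p = 0.00251, and 0.0508 without WT library 1), with Mmp2 and Eln called higher and Fbln5 lower over all genes and 0 called when adjusted over the list alone, and each of these 3 calls was lost in at least 7 of 10 fits with 1 library left out. Interferon response genes were higher in 10 of 12 members (median 0.47, adjusted p = 0.0231), with 0 called over all genes or adjusted over the list alone, and gave 0.0524 without WT library 2 and 0.0736 without WT library 4. The adjusted p of these 3 lists was 0.937 with an estimated correlation. Adipocyte markers were higher in 9 of 11 members (median 0.24, 0 called over all genes or adjusted over the list alone) and did not pass (adjusted p = 0.0565), though they did without KO library b (0.0296), KO e (0.0143), WT 1 (0.0321) or WT 5 (0.0147). Smooth muscle and pericyte markers were higher in 8 of 11 members (median 0.08, 1 called higher over all genes, Notch3, and 1 when adjusted over the list alone), with an adjusted p of 0.0565 that was 0.0386 without KO library b, 0.0417 without KO d and 0.0266 without WT 2. Fatty acid oxidation genes went the other way at the same adjusted p of 0.0565, lower in 16 of 20 members (median -0.22, 2 called lower over all genes, Hadhb and Acadm, and 2 when adjusted over the list alone), and passed without KO library a (0.00301), KO b (0.0316), KO d (0.0417), WT 1 (0.0397) or WT 5 (0.0312). Macrophage markers, with 7 of 21 members higher, a median of -0.28 and 0 called over all genes or adjusted over the list alone, did not pass (adjusted p = 0.785) but did as higher without WT library 5 (0.00197) or without the 2 libraries of lowest mean correlation (0.0111). Without KO library c, oxidative phosphorylation (0.00144, against 0.254; 2 members higher over all genes, 1 when adjusted over the list alone) and ribosomal protein genes (0.0117, against 0.254; 2 higher by either count) passed as higher, the latter also without WT 5 (0.0485). The 2 ribosomal protein genes called were Rps3a and Rpl34, whose fold changes (log2 4.67 and 3.84) are not read as expression. With all libraries 18 of 38 tested members of that list were higher (median -0.02, mean 0.20 with the 2 genes included). No rise of the list apart from these 2 genes is read from it. The count of muscle lists that passed was 5 with all libraries, 8 without KO library b, 8 without KO library c and 9 without WT library 5.

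With median-ratio scaling 529 muscle genes were higher and 499 lower, and with quantile normalisation 572 and 485, against a median log2 fold change of all muscle genes of -0.07 as deposited. Of 960 called muscle genes, 746 had no overlap between genotypes, and 10.5% of tested genes had none, where chance gives 0.79%. Of 70 called muscle genes under the naming rule, 50 kept the call with each library left out and 20 lost it at least once. Among genes tested in both tissues, 11 were called higher in both heart and muscle against 0.96 expected by chance, among them Dstn, Fbp2, Pdlim3, Prepl and Slc3a1. These 11 also include Rps3a and Rpl34, whose fold changes are not read as expression. Another 10 were called lower in both against 2.35 expected, among them Mbnl1, Ankrd23, Armetl1 and the mitochondrial reductase Mecr. Both expected counts treat heart and muscle libraries as coming from separate mice, which the labels do not settle. Rps3a and Rpl34 were the 2 calls of brain and were called in all 3 tissues.

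The KO effect itself differed between tissues for 10 of 9500 genes between heart and brain, 332 of 8654 between muscle and brain and 586 of 8898 between muscle and heart. Acta1 and Ankrd23 had effects lower in heart than in brain by 2.20 (log2 difference -2.20, adjusted p = 0.000543) and 2.04 (-2.04, adjusted p = 0.000543). Prepl had an effect 2.44 higher in muscle than in brain (adjusted p = 1.71e-11) and Pdlim7 one of -2.35 (adjusted p = 5.61e-07). The largest contrasts of muscle with heart by adjusted p were Osbpl3, an oxysterol-binding protein, at 2.53 (adjusted p = 4.5e-09), Mybpc2 at 2.07 (adjusted p = 7.36e-08) and the filamin Flnc at 2.37 (adjusted p = 4.58e-07). In simulated data 12.2% of calls of the muscle and heart contrast were false, and its count was 349 with a minimum of 5 RPKM and 226 without the 2 libraries of lowest mean correlation in each tissue. The heart and brain count was 27 without brain KO library a.

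Depletion of Mbnl1 in C2C12 cells left Mbnl1 at 27.0 RPKM against 108.7 in the control, and double depletion left 31.0. Mbnl2 stood at 18.1 RPKM after its own depletion, 24.4 after double depletion and 67.8 after Mbnl1 depletion, against 46.3 in the control. Footprints on Mbnl1 were 219 RPKM in the control, 16.4 after Mbnl1 depletion and 15.3 after double depletion, and those on Mbnl3 (Entrez 171170) were 21.9, 3.42 and 2.57. The 3 depletions share 1 control library per assay, so their changes are not independent of each other and no overlap between them is given.

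RNA of matrix genes was higher in each depletion than in the control, with a median log2 ratio of 0.82 for Mbnl1, 0.69 for Mbnl2 and 1.16 for both, above the random ranges, which reached at most 0.07. After Mbnl1 depletion the collagen genes Col6a1 (4.70 to 32.2 RPKM) and Col6a2 (0.84 to 9.84), the basement membrane gene Nid2 (22.4 to 88.6) and the crosslinking enzyme gene Lox (61.8 to 225) were among them. After double depletion the matrix glycoprotein gene Tnc went from 63.3 to 465 RPKM, and Pappa, a protease of insulin-like growth factor binding proteins, from 0.69 to 20.1. Cytoskeleton genes (0.21, 0.40 and 0.51), membrane receptors (0.23, 0.38 and 0.47), immediate early genes (0.42, 0.34 and 0.58) and known Muscleblind splicing targets (0.24, 0.41 and 0.52) also lay above their random ranges. Cnn1, a smooth muscle calponin, stood at 13.9 RPKM in the control, 67.3 after Mbnl2 depletion and 123 after double depletion. Ribosomal protein RNAs lay below their range in each depletion (-0.38, -0.39 and -0.57), and Nqo1, a quinone reductase, was at 110 RPKM in the control and 17.7 after double depletion. Changes of at least 2-fold in RNA numbered 160 up and 64 down of 8141 genes for Mbnl1, 65 and 35 of 8045 for Mbnl2, and 274 and 92 of 8119 for both.

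Footprints moved less than RNA for matrix genes, at 0.29, 0.21 and 0.31, so that footprints per RNA lay below the random range in each depletion (-0.39, -0.33 and -0.74). Col6a1 had the change of -2.49 after Mbnl1 depletion and -3.93 after double depletion in footprints per RNA, and Nid2 had -2.60 after double depletion. Immediate early genes were also lower in footprints per RNA (-0.58, -0.62 and -0.67), led by the transcription factor Egr1 at -2.22, -3.10 and -4.14. Ribosomal protein genes lay above the range in footprints per RNA after Mbnl2 depletion (0.54) and double depletion (0.39) and inside it after Mbnl1 depletion (0.21). ER chaperones and stress genes lay above it in each (0.29, 0.33 and 0.40), and Ddit3, a stress-induced transcription factor, had 2.36 after double depletion. Cell cycle genes had fewer footprints in each depletion (-0.48, -0.28 and -0.70), with 1, 4 and 2 of 33 members above 0, and Birc5, the mitotic survivin, had -1.68 after double depletion. Tnnt2, a troponin T and known Muscleblind splicing target, had RNA of 115 RPKM in the control and 51.6 after Mbnl1 depletion, with footprints of 10.9 and 25.8. Footprints per RNA changed at least 2-fold for 54 genes up and 107 down of 7357 after Mbnl1 depletion, 70 and 94 of 7267 after Mbnl2 depletion, and 251 and 364 of 7338 after both. The doubly depleted footprint library had 10458 genes above 0, against 10973 to 11195 in the other footprint libraries. It has no replicate, so its larger count is not read as a larger effect.

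**Figure D2:**
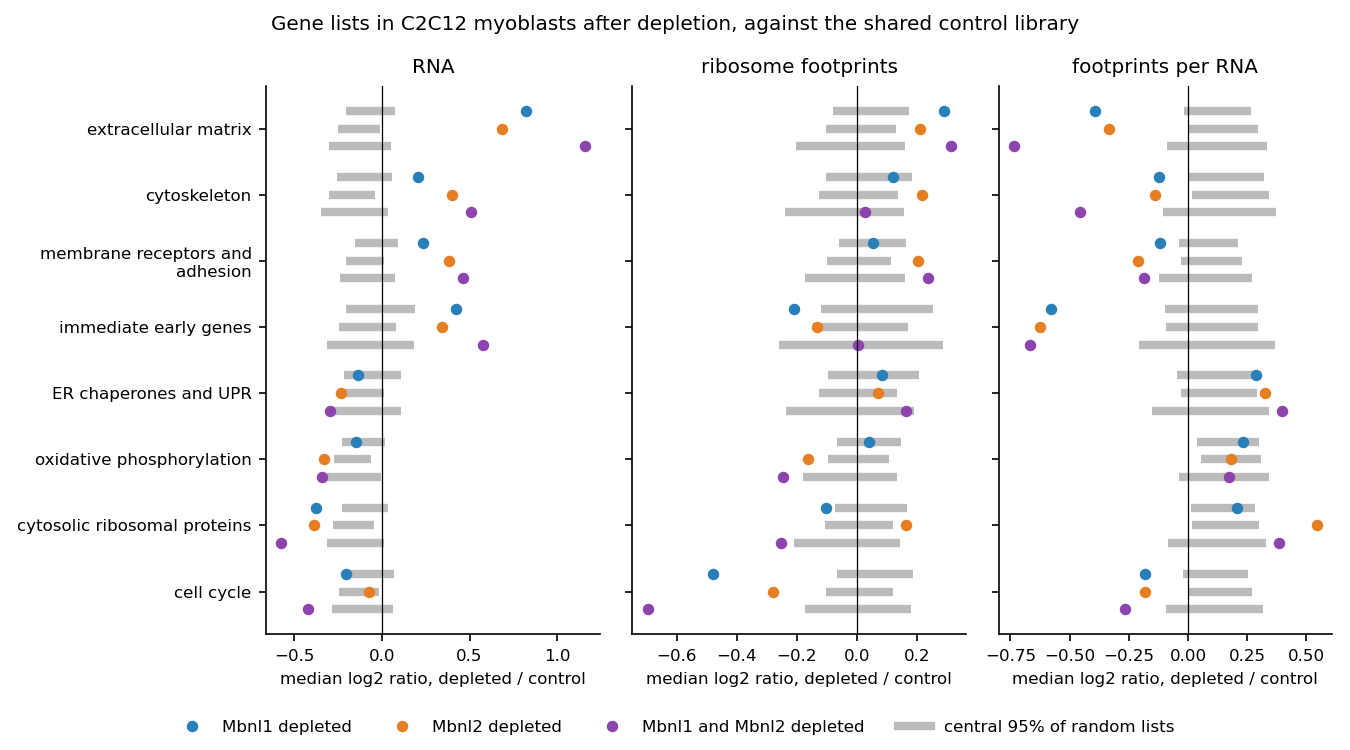
Median log2 ratio of depleted to control C2C12 cells (horizontal axes) for 8 gene lists in RNA, footprints and footprints per RNA, 1 library per condition. Grey bars are the central 95% of random lists, and matrix genes lie above them in RNA (0.69 to 1.16) and below them in footprints per RNA (-0.74 to -0.33).

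In control C2C12 cells, RNA of secreted and membrane proteins had higher ratios to the cytosolic fraction than other genes of like expression. Total RPKM was 430206 in cytosol, 247562 in membrane and 162424 in the insoluble fraction. Ratios are therefore read against other genes, not as the share of an RNA in a fraction. The median gene had a log2 ratio to cytosol of -0.68 in the membrane fraction and -1.27 in the insoluble fraction. Matrix genes stood at 1.14 and 2.75, membrane receptors at 0.78 and 2.17 and ER chaperones at 0.94 and 2.17, all above the random ranges, while ribosomal protein RNAs stood below at -1.28 and -2.79. Sparc, a matrix glycoprotein, had 53.4 RPKM in cytosol, 200 in membrane and 601 in the insoluble fraction, and Rpl37 had ratios of -2.02 and -4.48. Mbnl1 RNA had ratios of -0.97 and -1.75.

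After double depletion the ratio of membrane to cytosol was lower for matrix genes (median change -0.31, 3 of 27 members above 0), membrane receptors (-0.28, 5 of 33) and ER chaperones (-0.44, 1 of 21). The ratio of insoluble fraction to cytosol was higher for the same lists, at 0.28 (25 of 27), 0.19 (27 of 33) and 0.14 (16 of 21). Within fractions the median change of matrix genes was 0.03 in cytosol, -0.25 in membrane and 0.30 in the insoluble fraction. With 1 library per fraction and condition, a difference between preparations cannot be told apart from an effect of depletion. The basement membrane collagen gene Col4a2 had a membrane change of -0.94, the disulfide isomerase Pdia6 -0.90 and the hyaluronan receptor Cd44 -0.73. Other splicing regulators had lower ratios to cytosol in both fractions (-0.16 and -0.25), with Sfrs3 at -1.13. Both ratios use the same cytosolic libraries, so alike changes in them are not independent. The thymosin gene Tmsb4x, an actin monomer binder, had an insoluble change of -2.70 and cytosolic RPKM of 526 in the control and 2525 after depletion. Changes of at least 2-fold numbered 14 up and 41 down for membrane and 30 up and 62 down for insoluble RNA, of 7321 genes.

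In control fly cells the median gene already had a log2 ratio to cytosol of 1.52 in the membrane fraction and 1.195 in the insoluble fraction. Total RPKM was 3868546 in cytosol, 2339667 in membrane and 1340372 in the insoluble fraction. The 10 most abundant genes took 22.2%, 9.59% and 5.43% of it, so the ratios depend on the scale and make-up of each fraction. Receptor RNA stood higher than the median gene, with medians of 2.75 and 4.61, above the random ranges. Of 6 fly lists, 1 lay above its range in membrane and 3 in the insoluble fraction. The laminin gene LanA had 4.31 and 7.84, the collagen gene vkg 4.46 in membrane and the receptor tyrosine kinase gene Pvr 4.59 in membrane. Ribosomal protein RNAs stood at -1.96 and -4.75, with RpS26 at -2.51 and -6.16. The targeted mbl RNA was listed at 0 in cytosol, stood at 5.50 and 1.57 RPKM in the membrane fraction of control and depleted cells, and at 43.4 and 5.04 RPKM in the insoluble fraction.

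After mbl depletion, ER chaperone RNAs had lower ratios to cytosol in membrane (median change -0.26) and insoluble fractions (-0.44, 2 of 14 members above 0), both below the random ranges. Cytoskeleton RNAs had higher ratios (0.36 and 0.44, 11 of 14 members above 0 in both), with the actin gene Act42A at 1.20 and 1.38. Both ratios use the same cytosolic libraries, so alike changes in membrane and insoluble fraction can be a single cytosolic difference. Control and depleted log2 values correlated by 0.9944 in cytosol, 0.9987 in membrane and 0.9984 in the insoluble fraction. Fly receptors and secreted proteins stayed inside their random ranges in both fractions. Ribosomal protein RNAs lay below in the insoluble fraction (-0.12, range from -0.11) and inside in membrane (-0.04). Changes of at least 2-fold numbered 157 up and 113 down for membrane and 138 up and 143 down for insoluble RNA, of 6577 genes. The polymerase Parp had a membrane change of 2.07.

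**Figure D3:**
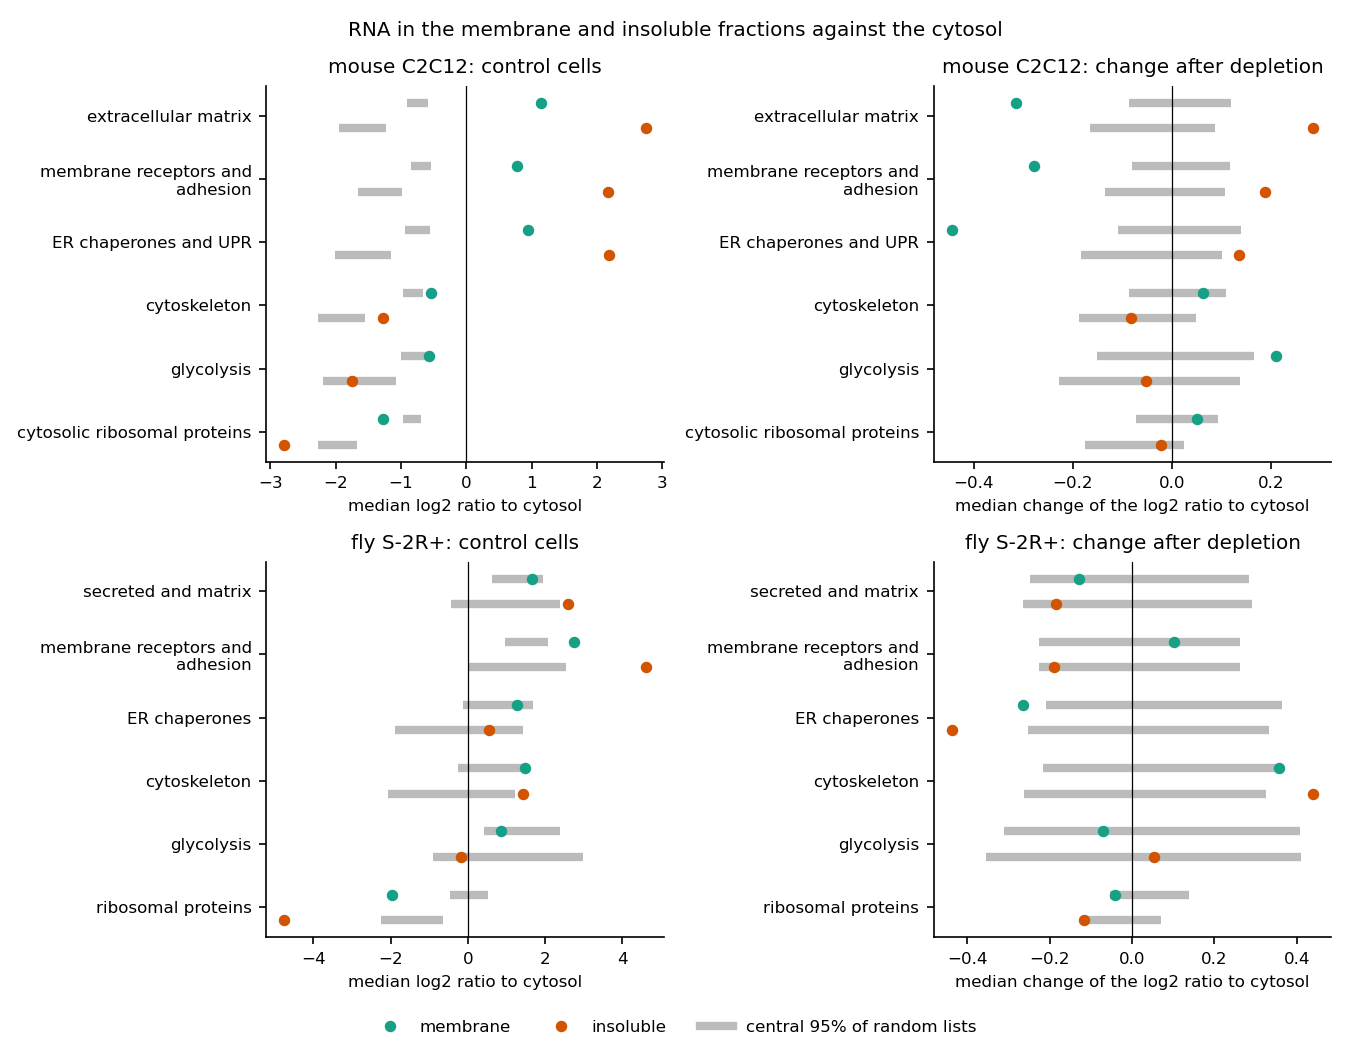
Median log2 ratio of membrane (green) and insoluble RNA (orange) to cytosol in control cells, left, and its change after depletion, right, for gene lists of mouse C2C12 cells and fly S-2R+ cells, 1 library per condition. Grey bars are the central 95% of random lists; mouse ER chaperones change by -0.44 in membrane and 0.14 in the insoluble fraction, fly ones by -0.26 and -0.44.

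The CLIP lists held 3177 clusters in B6 brain, 11580 in 129 brain, 645 in heart, 443 in muscle and 24191 in C2C12 cells, over 1445, 3649, 461, 340 and 5590 genes. Clusters on the Mbnl family numbered 4 in B6 brain, 12 in 129 brain, 2 in heart, 4 in muscle and 94 in C2C12 cells, of which 68 in C2C12 cells lay on Mbnl1 itself. The B6 brain cluster on Mbnl1 spanned positions 60430746 to 60430781 of chromosome 3 on the plus strand of mm9, counted from 1. Of 35 known Muscleblind splicing targets, 13 had clusters in B6 brain, 18 in 129 brain, 6 in heart, 8 in muscle and 18 in C2C12 cells.

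Clusters recurred between tissues above the shifted background. Of B6 brain clusters 48.9% (95% Wilson interval 47.1% to 50.6%) overlapped a 129 brain cluster, against 3.95% after shifting. Of heart clusters 17.7% (14.9% to 20.8%) overlapped B6 brain and 22.3% (19.3% to 25.7%) overlapped C2C12 clusters, against 0.89% and 1.8% after shifting. Of muscle clusters 9.93% (7.48% to 13.1%) overlapped heart clusters and 21.0% (17.5% to 25%) C2C12 clusters, against 0.25% and 1.52%. With an overlap of at least 50% of the shorter cluster the share of B6 brain in 129 brain was 42.6%. Of B6 brain clusters 18.8% overlapped C2C12 clusters, the longest list.

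**Figure D4:**
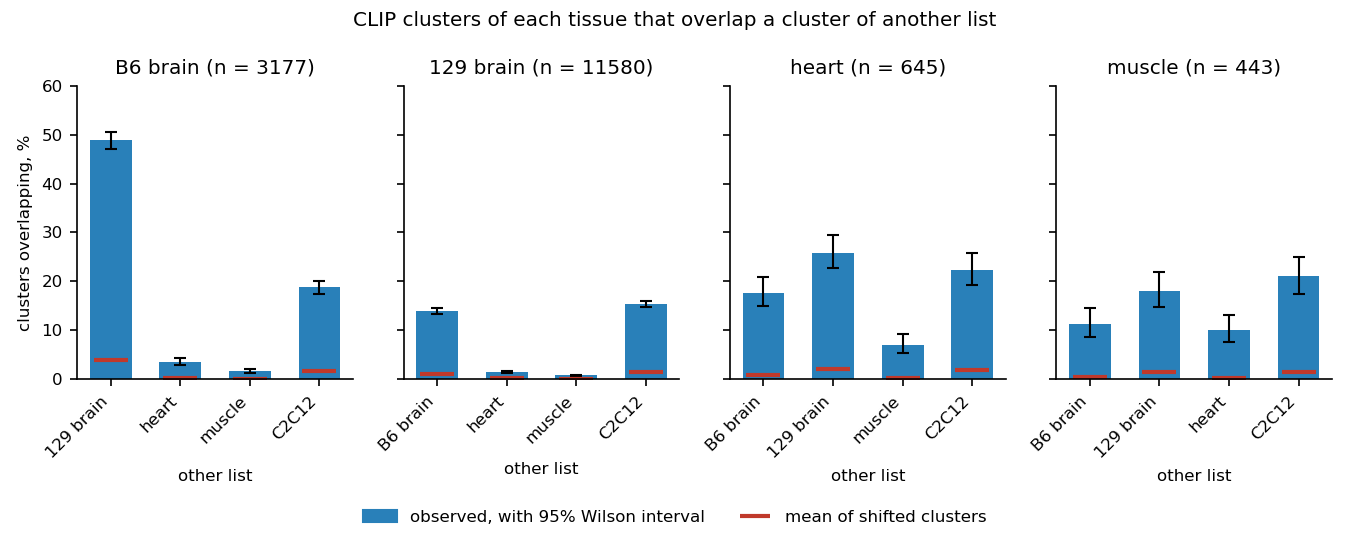
Share of clusters (percent, axis from 0) of each tissue list that overlap a cluster of another list on the same strand, with 95% Wilson intervals, and the mean share after shifting the clusters (red). B6 brain clusters reach 48.9% in 129 brain and 3.53% in heart.

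Genes with clusters were more often abundant, from 1.2% of genes in the lowest 10% by expression to 37% in the highest 10% in B6 brain. Against genes matched on expression, bound genes lay lower in KO brain (median -0.10 for B6 clusters, random range -0.05 to -0.04) and KO heart (-0.12, range -0.07 to -0.02), and inside the range in muscle (-0.13). Permuting genotype gave no difference in excess for bound genes in brain (exact p = 0.698 for B6 and 0.667 for 129 clusters), heart (exact p = 0.278) or muscle (exact p = 0.667), so none holds up against the variation between libraries. In doubly depleted C2C12 cells, bound genes had RNA ratios of 0.00 against random medians of -0.06, and footprints per RNA of 0.00 against 0.07, above and below the ranges.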

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

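The tests of other splits, of Rps3a, Rpl34 and Selenbp2, of genotype and depth in heart KO library a and of the shared control were chosen only after the results were seen.

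Genotype was set against other splits of the same libraries, with 100 of 126 splits drawn per tissue and the real one included. The real split of brain gave 2 genes and the highest other 1, that of heart 77 and 34, and that of muscle 960 and 1. In each tissue 1 of 100 splits, the real one, reached the count. This argues against chance but cannot exclude it, since 1 of 100 is the smallest share possible here. The 2 brain genes were Rps3a and Rpl34, whose fold changes are not read as expression. For gene lists chance stays open, since 70, 85 and 61 of 100 splits gave as many lists as the 4, 4 and 5 called in brain, heart and muscle. Up to 13, 13 and 10 lists passed in another split. For the difference in KO effect, 1 of 100 splits reached the count in each contrast, with 10 genes between heart and brain (highest other 3), 332 between muscle and brain (3) and 586 between muscle and heart (536).

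Rps3a and Rpl34 separated KO from WT in all 3 tissues, and Selenbp2 did so in heart, where it was listed at 0 in KO. These 3 genes lie on chromosome 3, as Mbnl1 does. Of ribosomal protein genes on other chromosomes that reached the expression minimum in all 3 tissues, 0 of 36 separated the genotypes in all 3. This cannot decide whether reads shared between paralogs play a part, since genes that lose their reads fall under the minimum and were not tested. In brain 39 of 74 ribosomal protein genes reached it. Of other genes with a transcript no longer and a mean of 0.5 to 1 times that of 1 of these genes, 1 of 593 pairs of gene and tissue was near 0 (at most 0.66 RPKM) in all libraries of the other genotype, which argues against a difference in depth. This test replaced an earlier one on the depth of single libraries after its value was seen, which by its own criterion left depth open: of 35 values of the 3 genes near 0, 2 came from a library shallower than every library of the other genotype, both from heart WT library 5. Sequence of another strain around the deleted gene, carried along in the KO line, is a candidate explanation that these tests did not settle. Without these 3 genes the called share on chromosome 3 was 7 of 483 against 65 of 9803 elsewhere in heart (Fisher's exact p = 0.0824) and 48 of 440 against 906 of 8764 in muscle (p = 0.689). For Selenbp2 it cannot be told apart from an effect of Mbnl1. For Rps3a and Rpl34 an effect of Mbnl1 on expression would need WT tissue almost without their RNA, which is not believable, as stated for brain. The other 8 of 10 chromosome tests gave Fisher's exact p = 0.03 for genes that separated in all 3 tissues (2 of 404 against 4 of 8066), 0.00245 in brain, 0.00264 in heart (10 of 486 against 65 of 9803) and 0.522 in muscle with the 3 genes kept, 1 in brain without them, and 1, 0.165 and 0.324 in brain, heart and muscle for the 100 tested genes nearest to Mbnl1. In brain 0 of these 100 genes were called, so Rps3a and Rpl34, the 2 calls there, are not among the nearest.

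Heart KO library a lay apart from the other KO hearts, and without it 191 genes were called in place of 77. Its interferon response genes lay 0.85 above the other KO hearts in median, and its ribosomal protein genes at -0.48. Mbnl1 stood at 19.42 RPKM in it, against 30.39 to 46.46 in WT hearts (SD 6.33) and 8.97 to 16.89 in the other KO hearts, which argues against a wild-type heart under a KO label. Its relative depth was 1 within 0.69 to 1.03 for the other KO hearts, which argues against depth. RNA from other cell types could not be told apart, since 1 of 5 marker lists lay outside the random range in it and up to 4 did in another heart library. An animal with an interferon response may be the source, and was not tested.

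Matrix genes were higher in RNA and lower in footprints per RNA after each C2C12 depletion. With the trend on transcript length and GC content removed, the median RNA change of the list was at least 0.493 and above the random range in the 3 depletions, which argues against that trend as the whole cause. The shared control RNA library as the source cannot be told apart, since in the fractions, which have another control, the list changed by 0.03 in cytosol, -0.251 in membrane and 0.30 in the insoluble fraction. A response of these cells to loss of Mbnl stays open.

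The KO effect on single genes differed between tissues, with the 5 smallest adjusted p per contrast as follows. Heart minus brain was -2.04 for Ankrd23, -2.20 for Acta1, 1.69 for BC057371, -1.67 for Cabc1 and 1.12 for Slc3a1. Muscle minus brain was 2.44 for Prepl, 2.49 for Slc3a1, 2.28 for Osbpl3, 1.78 for Tbc1d1 and -2.35 for Pdlim7. Muscle minus heart was 2.53 for Osbpl3, 2.07 for Mybpc2, 2.37 for Flnc, 1.53 for Prepl and 1.74 for Tbc1d1.

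Single libraries lay far from the others of their group in 23 of 228 groups of 5 values tested (10.1%, where chance gives 5%). By mean correlation these were brain KO a at 0.9166 (next 0.9581), heart WT 5 at 0.9139 (next 0.9533) and heart KO c at 0.9604 (next 0.9562). Brain WT 3 had 3.72% of RPKM in its 10 most abundant genes (next 3.39%), and muscle WT 5 had 11898 genes above 0 (next 11537). In brain, Rps3a stood at 33.73 RPKM in KO a (next 11.56) and 0.25 in WT 4, and Rpl34 at 0.66 in WT 3. In heart, KO b had Rps3a at 33.27 (next 25.65) and Fbp2 at 18.61 (20.67), KO a had Armetl1 at 4 (2.58), Ankrd23 at 116.42 (92.03) and Myh7b at 20.29 (10.67), WT 3 had BC057371 at 0.34 (0.65) and Ankrd1 at 1371.5 (937.17), and WT 4 had Mybpc2 at 15.21 (12.51). In muscle, WT 1 had Bnip3 at 21.98 (10.97) and Hcn2 at 0.87 (0.65), WT 4 had Aldh1l1 at 2.46 (2.69), WT 5 had Avil at 7.65 (3.48) and Cd3e at 0.62 (1.18), KO c had Ctsl at 56.48 (67.84) and KO e had Xbp1 at 64.54 (40.2).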

How the results depend on the processing

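The alternatives chosen after seeing the data left out the 2 libraries of lowest mean correlation, the chromosome of Mbnl1, or Rps3a and Rpl34, or matched on gene length. For single genes of tissues and tissue contrasts, 1121 of 1346 results were the same with 1 library left out. Under other settings 1045 of 1123 were. The rest were weaker, and both shares include genes not called with all libraries. With each library left out, 2 of 2 named and called genes in brain, 15 of 29 in heart and 50 of 70 in muscle kept the call. So did 5 of 5 in each tissue contrast. For tissue lists 670 of 729 and 529 of 571 were the same, a share that includes lists not called with all libraries. Of the called lists, 0 of 4 in brain, 2 of 4 in heart and 3 of 5 in muscle kept the call with each library left out. In C2C12 lists 486 of 514 were the same, in C2C12 genes 2237 of 2277, in fly lists 41 of 44, in fly genes 390 of 390 and in CLIP values 56 of 65. Read depth is unknown, so genes near the expression minimum have an unstated counting error.

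With 1 library left out, heart genes numbered 25 (without KO c) to 191 (without KO a), heart lists 3 to 7, muscle lists 4 to 9 and genes of the brain and heart contrast 7 to 27. The p of oxidative phosphorylation in brain ran from 8.35e-06 to 0.0439, of glycolysis in brain from 0.00518 to 0.94 and of macrophage markers in heart from 6.48e-05 to 0.735. Directions reversed without brain KO a (camera gave 0.0169 for oxidative phosphorylation and 0.00518 for glycolysis) and without heart WT 5 (6.48e-05 for macrophage markers). Without the 2 libraries of lowest mean correlation, oxidative phosphorylation in brain (0.0278) and macrophage markers in heart (0.000101) reversed, and counts were 51 heart genes, 597 muscle genes, 10 muscle lists, 16 genes for brain and heart and 226 for heart and muscle. The cause was not tested.

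A joint fit of 30 libraries called 7 brain and 221 heart genes, and library weights called 44 and 326, from a spread pooled or weighted otherwise. Without chromosome 3, which holds Rps3a and Rpl34, 0 brain genes were called. Camera with an estimated correlation called 0 lists in brain, 0 in heart and 0 in muscle, and fry called 0, 1 and 2. With a minimum of 5 RPKM, fewer genes were tested, giving 1 brain gene, 2 brain lists, and 5, 217 and 349 genes for brain and heart, brain and muscle, and heart and muscle. With no minimum the first was 25. With the replicate block as a fixed factor the 3 contrasts gave 7, 281 and 430 genes, and as a correlation 10, 314 and 552. Profiles of libraries with one label in 2 tissues correlated by a median of 0.03, above 0.1 in 9 of 30 pairs and best with their own label in 10. WT 5 was best with its own label in each pair of tissues (0.125, 0.145 and 0.541), as were heart and muscle WT 1 (0.279) and WT 3 (0.203), so whether labels mark mice stays open.

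For C2C12 cells the expression minimum set the number of genes counted. At 1 RPKM, 2-fold changes numbered 351 in RNA for Mbnl1, and 263, 305 and 1077 in footprints per RNA for Mbnl1, Mbnl2 and both. At 20 RPKM they were 99, 41 and 172 in RNA and 66, 66 and 216 in footprints per RNA. Changes of the C2C12 membrane ratio numbered 87 with a pseudocount of 0.1, 116 at 1 RPKM and 19 at 20 RPKM, and those of the fly ratio 409 with a pseudocount of 0.1. An overlap of 50% of the shorter cluster gave 42.56% for B6 in 129 brain. The planned CLIP settings not run were a split by score, since it is constant, and 3' untranslated regions, since the region of clusters is not given.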

Other observations

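Heart WT library 5 carried macrophage and microglia markers above the other 4 WT hearts, by a median of 2.58 on the log2 scale (22 members, random range -0.19 to 0.14). Emr1, the F4/80 antigen of macrophages, stood at 145.41 RPKM against 1.47 to 3.33 in the other 9 hearts. The lymphoid and myeloid surface gene Cd52 stood at 207.31 RPKM against 1.1 to 3.46, the lysosomal Laptm5 at 144.79 against 6.4 to 13.27, the integrin gene Itgam at 27.49 against 0.8 to 2.03 and the complement gene C1qa at 135.82 against 31.06 to 43.27. Interferon response genes lay 0.80 above the other WT hearts in the same library and atrial markers at -0.39. The library and the genes named here were chosen after their values were seen.

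Ucp1, the uncoupling protein of brown fat, ranged from 2.88 to 98.1 RPKM in WT hearts and from 0.25 to 17.56 in KO hearts. Genes that separated KO from WT in all 3 tissues besides Rps3a and Rpl34 were Flywch1, Unc84b, Lpin1 and Ctr9, all lower in KO. These genes and Ucp1 were named after their values were seen.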
